A study of Homo sapiens with 9 samples.

How the data were processed

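Gene expression was measured in 3 established human embryonic stem cell (hESC) lines, H14, Shef1 and Shef3, on Affymetrix oligonucleotide arrays read at the 3' end of transcripts. Per the labels, undifferentiated cells were kept on mouse embryonic fibroblast feeders in serum replacement medium with 4 ng/ml basic FGF and were taken at day 0. For differentiation they were dissociated, plated on laminin and kept for 14 days in DFNB, a serum-free medium with N2 and B27 supplements, either alone or with FGF3 and FGF10 at 50 ng/ml each. Per the labels' protocols, 200 ng of total RNA was amplified and labelled with biotin. There were 9 arrays, 1 per cell line in each of 3 groups named hESC, DFNB and FGF3+10. Each group therefore held 3 arrays that differ in cell line, and the spread within a group includes differences between lines. Replicates 1, 2 and 3 in each group are Shef3, H14 and Shef1.

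The deposited values are on a log scale, taken here as log2, and the authors set every array to a median of 3.20 over the probe sets. The software, the summary of probes into probe sets and the background correction are not given in the sources used here, and no source states the base of the logarithm. The hybridisation spike-ins from bioB to cre spanned 5.00 units against 6.06 doublings of their nominal dose, or 4.20 in natural logarithm units, and the slope was 0.834 units per doubling. The span lies between these values and nearer to that of the natural logarithm, so the spike-ins do not settle the base. Log2 is thus an assumption, and a change of 1 unit is called a log2 change of 1 throughout. Shares of a level kept depend on that assumption. Values had no lower bound: they ranged from -14.4 to 13.3. The median spread (SD) within groups was 0.968 for genes with a mean level below 0, against 0.312 for genes above 10, so low values carry much of the noise. No detection calls were used here. Microarray values have no read depth, and the number of arrays limits the precision.

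The table held 54675 probe sets, of which 62 were controls. Of these, 41091 had 1 gene symbol in the platform annotation, 1801 had several, and 11721 other than controls had no gene in the table used. Symbols were updated through Entrez identifiers, of which 41037 matched. For each gene the probe set with the highest mean over the 9 arrays was taken, without regard to group, and 10511 genes had more than 1. No gene was named from a probe set with several symbols. After leaving out 35 Y-linked genes and XIST, 19740 genes were tested. Of the genes called between DFNB and hESC, 15 had several probe sets, and 5 of them had a probe set whose change had the opposite sign. Between FGF3+10 and hESC it was 3 of 11. POU5F1 had no probe set with a single symbol and was not analysed here by gene. Some other list members are not reported here.

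Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the log2 values with a mean for each group and 1 shared estimate of the spread over all 9 arrays. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p below 0.05. Differences between cell lines were tested with the moderated F test in a model of group and line. Before the data were examined, 28 gene lists were fixed, among them markers of cell types that such cultures could hold. Lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and adjusted over the lists. Counts of list members are given over all genes and adjusted over the list alone.

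The genes named in the text follow a rule fixed at the same time. It takes the 10 largest rises and the 10 largest falls among called genes with the same sign in all 3 lines, or, where none passed, the 5 with the highest moderated t in each direction as values. It takes up to 4 called members of each list discussed, or else the 2 members with the largest absolute change as values. It always takes a set of pluripotency, otic and FGF response genes, and for the cell lines the 6 genes with the largest F. Genes named outside it are said to be chosen after their values were seen.

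The same cell line occurs in every group, so the lines pair the arrays by the cell line label. Deviations from the group means correlated within lines at 0.104, 0.0834 and 0.338 between DFNB and hESC for Shef3, H14 and Shef1. They correlated at 0.181, 0.256 and 0.283 between FGF3+10 and hESC, and at 0.401, 0.329 and 0.714 between FGF3+10 and DFNB. The highest correlation of a DFNB array with an hESC array of another line was 0.0811 for Shef3, 0.175 for H14 and -0.132 for Shef1. For H14 it thus exceeded that within the line, and for Shef3 it came close. In the other comparisons the correlation within the line was the higher one for every line. The main model has no block, as fixed beforehand, and the value with the cell line as replicate block is given where it changes a call or moves a count by more than 1.5 times.

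Other alternatives were quantile normalisation, centring, a filter on dim genes, other choices of probe set, a random block, a trended and robust variance, array weights, the 6 arrays of a comparison alone, and leaving out each array or line. Chosen after seeing the data were a floor of 4, which set every value below 4 to 4 and left 13391 genes, that floor with the block, the trended and robust variance with the block, the paired fit of 6 arrays, and a test of whether the day 14 change differed between lines. This last test took the DFNB and FGF3+10 arrays of a line as its 2 day 14 arrays, which leaves 3 residual degrees of freedom and counts any effect of the FGFs as noise.

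The methods were tested on simulated log2 values with the means and spreads of the 19740 genes, with 200 genes changed in the DFNB against hESC comparison in each of 5 draws. Without the block, 30.4% of planted changes of 2, 84.8% of those of 4 and 98.4% of those of 6 on the log2 scale were called, and 4.69% of calls were false. With the block the shares were 14.8%, 82.4% and 96.0%, and 5.66% of calls were false. The simulated noise had no cell line differences and no correlation between genes. In the cell line F test, 95.7% of genes moved by 6 in 1 line were called. Figures were drawn with matplotlib 3.10.9.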

Results

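The series profiled hESC lines before and after differentiation towards otic progenitors, the cells of the early inner ear. Per its design, undifferentiated cells at day 0 were set beside cells kept for 14 days in DFNB medium alone or in DFNB with FGF3 and FGF10, signalling proteins that act in the formation of the otic placode. Each of 3 groups held 3 arrays, 1 each of Shef3, H14 and Shef1. The lower and upper quartiles of the arrays lay between 0.365 and 0.606 and between 6.02 and 6.46 around the common median of 3.20. Pearson correlations between arrays across genes, which are not independent replicates, ran from 0.901 to 0.977. The highest joined the DFNB and FGF3+10 arrays of Shef1. The first principal component held 38.2% of the variance and the second 20.8%. On the first, the day 14 arrays of Shef3 stood at 106 and 106 and DFNB H14 at 84.9, against -65.2, -81.4 and -95.2 for the hESC arrays. FGF3+10 H14 stood at 29.7, and the Shef1 day 14 arrays at -29.2 in DFNB and -55.5 in FGF3+10.

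The signal of the GAPDH control probe sets at the 3' end exceeded that at the 5' end by 0.14 to 0.53 log2 units on the 9 arrays, and that of ACTB by 0.08 to 0.69. The GAPDH difference averaged 0.19 ± 0.01 (SD, n = 3) in DFNB and 0.33 ± 0.17 in hESC, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow, and of 0.2 after quantile normalisation. The other 5 exact tests of group pairs gave 0.4 to 0.9, and such tests cannot show that RNA quality was alike. The poly-A spike-ins, bacterial transcripts added before labelling, averaged 7.45 ± 0.04 (SD, n = 3 arrays) on the Shef1 arrays, 5.34 ± 0.06 on H14 and 5.33 ± 0.35 on Shef3. Their difference between Shef1 and the other lines was 2.12 log2 units, and no other array reached the lowest Shef1 value of 7.43. The hybridisation spike-ins averaged 9.41 ± 0.10 on Shef1, 9.83 ± 0.22 on H14 and 9.81 ± 0.40 on Shef3.

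**Figure D1:**
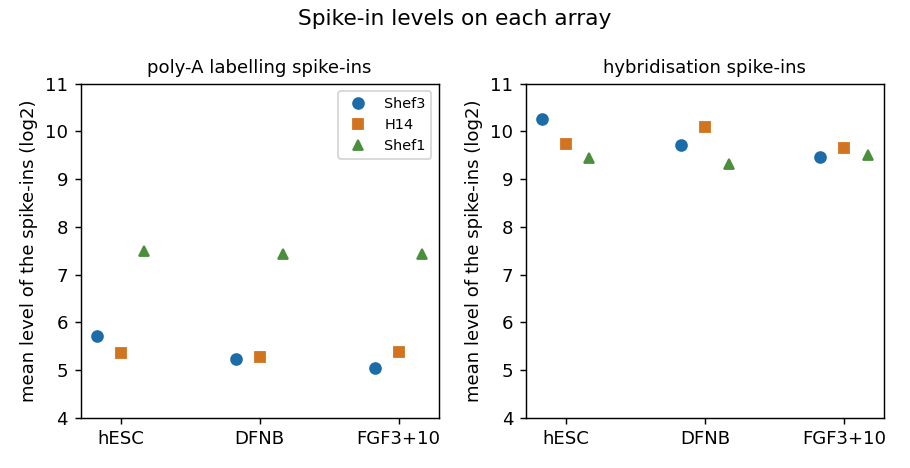
Mean level (log2) of the poly-A labelling spike-ins and of the hybridisation spike-ins on each of the 9 arrays, by group, with 1 point per cell line. The 3 Shef1 arrays have poly-A levels of at least 7.43, and the highest of the other arrays is at 5.72.

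The first comparison asks what changed over 14 days in DFNB medium without added FGFs. DNMT3L, a cofactor of de novo DNA methylation, fell from 5.81 ± 1.15 (SD, n = 3) in hESC to -3.61 ± 1.08 in DFNB. NLRP7, a gene of the oocyte and early embryo, fell from 4.57 ± 0.81 to -2.96 ± 0.84, and S100A14, an epithelial calcium-binding protein, from 7.58 ± 0.36 to 2.84 ± 0.61. FOXE3, a transcription factor of the lens, rose from -2.71 ± 0.39 to 6.58 ± 2.84. CLSTN2, a synaptic cadherin-related protein, rose from 3.31 ± 0.88 to 8.57 ± 0.49, and GFRA1, a receptor for GDNF, from 3.22 ± 1.00 to 7.50 ± 0.62. Each of these changes had the same sign in all 3 lines.

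In total 40 of 19740 genes were called, 23 higher and 17 lower in DFNB. At an unadjusted p below 0.05 there were 3121, against 987 expected by chance. With the cell line as replicate block 189 genes were called, 100 higher and 89 lower, of which 39 were among the 40. The share of higher genes differed with the setting, at 88 of 110 without dim genes and 614 of 1647 with array weights. The count was 0 without Shef3, 0 without H14 and 4 without Shef1, in fits with fewer arrays in every group. At an unadjusted p below 0.05 these fits gave 1988, 1330 and 4183 genes, so that number rose without Shef1. Without a single array the number of genes called was 6 (hESC H14), 9 (hESC Shef1), 4 (DFNB Shef3), 13 (DFNB H14), 8 (DFNB Shef1), 72 (FGF3+10 Shef3, which enters through the shared spread) or 25 (FGF3+10 H14). Both groups' means lay below level 4 for 10 of the 40 genes and 1 group's mean for 22. With the floor of 4, chosen after seeing the data, 184 genes were called, 19 of them among the 40. The median log2 change over all genes was -0.19, and -0.08 after quantile normalisation, so changes are to be read relative to that shift. The GAPDH 3' to 5' difference moved by -0.14 log2 units from hESC to DFNB (exact permutation p = 0.1).

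Among the 10 largest rises, the log2 change was 9.29 ± 1.22 (SE, n = 3 and 3 arrays) for FOXE3 (adjusted p = 0.0287). ZFHX4-AS1, an antisense RNA, rose by 6.99 ± 0.58 (adjusted p = 0.00555), and the neural adhesion genes CNTN6 and CNTN5 by 6.27 ± 0.64 and 4.04 ± 0.56. CLSTN2 rose by 5.26 ± 0.58 (adjusted p = 0.0184), TSPAN11 by 4.96 ± 0.48 and LOC101927263 by 4.76 ± 0.69. ADAMTS18, a secreted protease, rose by 4.56 ± 0.62, WNT5B, a WNT ligand, by 4.30 ± 0.54, and GFRA1 by 4.28 ± 0.53. LOC101927263 had an adjusted p of 0.0476, and of 0.0529 with the block. Among the 10 largest falls, DNMT3L fell by 9.42 ± 0.69 (adjusted p = 0.00412), NLRP7 by 7.53 ± 0.52 (adjusted p = 0.00412) and PDZK1, a scaffold of epithelial transporters, by 7.04 ± 0.84. NRROS fell by 5.34 ± 0.62, S100A14 by 4.74 ± 0.51 and DPPA5, a gene of pluripotent cells, by 4.69 ± 0.36. NOSTRIN fell by 4.22 ± 0.58, LINC02585 by 4.10 ± 0.50, RNF5 by 3.71 ± 0.48 and DHX58, an antiviral RNA sensor, by 3.70 ± 0.45.

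The size of several of these changes rests on low values. With values below 4 set to 4, the log2 change was 2.81 for FOXE3, 2.79 for ZFHX4-AS1, 2.00 for CNTN6, 4.57 for CLSTN2, 2.31 for TSPAN11, 0.39 for LOC101927263, 2.61 for WNT5B and 0.35 for CNTN5. It was -1.81 for DNMT3L, -0.67 for NLRP7, -1.75 for PDZK1, -0.63 for NRROS, -0.72 for RNF5 and -3.58 for S100A14. DPPA5, NOSTRIN, LINC02585 and DHX58 lay below 4 on all arrays of both groups. With that floor the calls of FOXE3 (adjusted p = 0.218), CNTN6 (0.0986), LOC101927263 (0.459), CNTN5 (0.588), DNMT3L (0.114), NLRP7 (0.260), NRROS (0.297) and RNF5 (0.0971) were lost, and the other 8 tested held, among them CLSTN2 (0.00678) and S100A14 (0.00223).

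**Figure D2:**
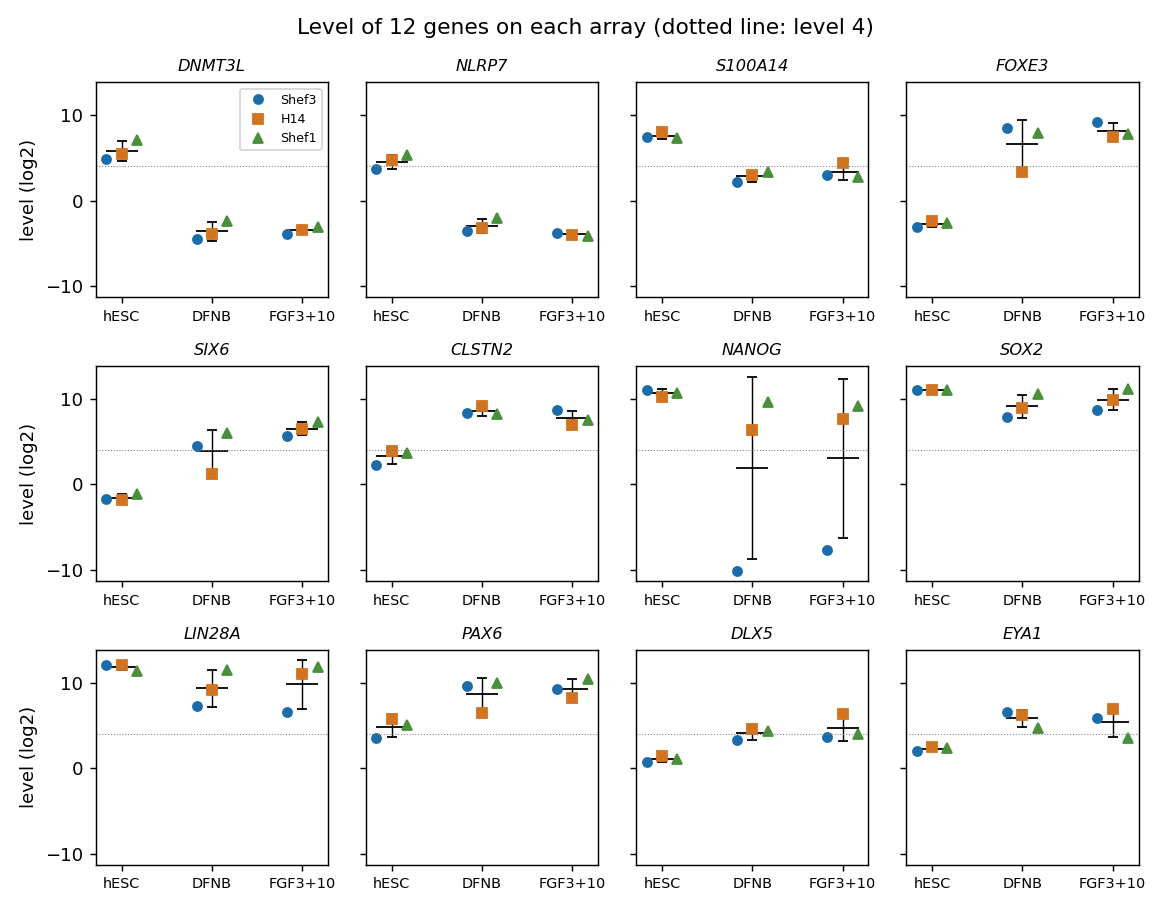
Level (log2) of 12 genes on each of the 9 arrays, by group, with 1 point per cell line, a bar at the group mean and whiskers of 1 SD (n = 3). DNMT3L and NLRP7 fell in every line, whereas the NANOG levels in DFNB run from -10.2 on the Shef3 array to 9.64 on the Shef1 array.

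Of 25 measured pluripotency genes none passed over all genes or adjusted over the list alone. All 25 were lower on average, and the median log2 change was -2.98. By line it was -4.81 in Shef3, -2.80 in H14 and -0.58 in Shef1. The list was called lower by camera (adjusted p = 1.20e-06; adjusted p = 0.471 with an estimated correlation). In a test chosen after seeing the data, camera called its day 14 change different between Shef1 and Shef3 (adjusted p = 1.58e-08), H14 and Shef3 (1.81e-08) and Shef1 and H14 (0.0230). None of these held with an estimated correlation (adjusted p = 0.839 for each) or with fry (adjusted p = 0.190, 0.241 and 0.609). The spread in that test came only from the 2 day 14 arrays of each line, which differ in medium. Its p-values therefore do not measure the variation between repeats of a line. NANOG, a core pluripotency factor, averaged 10.68 ± 0.45 in hESC and 1.93 ± 10.61 in DFNB, with a change of -21.27 in Shef3, -3.88 in H14 and -1.10 in Shef1 (adjusted p = 0.468). Its other probe set went from 8.28 to -0.93 in Shef3, 7.81 to 3.68 in H14 and 8.32 to 6.53 in Shef1. PRDM14 had a change of -7.50 ± 3.39 (adjusted p = 0.329). With the floor of 4 the changes of NANOG and PRDM14 were -4.03 and -3.91. SOX2, shared by pluripotent and neural cells, had a change of -1.94 ± 0.77 (adjusted p = 0.283). The poly-A spike-ins stood higher on the Shef1 arrays, where these levels were also the highest at day 14.

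Of 24 endoderm genes none passed over all genes and 12 fell when adjusted over the list alone. Their median change was -2.56, with -2.74 in Shef3, -2.39 in H14 and -1.69 in Shef1 (adjusted p = 8.00e-07; adjusted p = 0.143 with an estimated correlation). CER1 and FOXA2 had changes of -7.05 ± 2.30 and -5.77 ± 1.41 (adjusted p = 0.212 and 0.128), or -4.26 and -2.31 with the floor.

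Of 32 neural progenitor genes none passed over all genes, and 15 rose and none fell when adjusted over the list alone. The median was 1.59, with 1.56 in Shef3, 1.20 in H14 and 1.63 in Shef1 (adjusted p = 5.19e-11; adjusted p = 0.0625 with an estimated correlation). SIX3 and SIX6, factors of the eye field and forebrain, had changes of 5.89 ± 1.44 and 5.46 ± 1.07 (adjusted p = 0.128 and 0.0797), or 2.74 and 0.86 with values below 4 set to 4. PAX6, a factor of the eye and forebrain, had a change of 3.87 ± 1.01 (adjusted p = 0.147). Of 30 otic and preplacodal genes none passed over all genes, and 10 rose and 1 fell when adjusted over the list alone. Their median was 1.01 (adjusted p = 8.00e-07; adjusted p = 0.138 with an estimated correlation), but 0.07 with values below 4 set to 4, since 12 of the 30 averaged below 4 (adjusted p = 0.000954 with that floor). EYA4 and EYA2 had changes of 4.96 ± 1.10 and 4.55 ± 0.80, and EYA1 of 3.57 ± 0.83 (adjusted p = 0.102, 0.0652 and 0.112). With the floor the changes of EYA4, EYA2 and EYA1 were 1.07, 1.60 and 1.86. EYA2 passed with the block (adjusted p = 0.0416), and so did DLX5, a factor of the preplacodal region, with a change of 3.02 ± 0.70 (adjusted p = 0.112, and 0.0499 with the block), which was 0.35 with the floor (adjusted p = 0.764). PAX8, an early otic factor, had a change of -0.38 ± 0.40, PAX2 of 1.10 ± 0.95 (0 with the floor) and GATA3 of 1.53 ± 0.62, and none of the 3 passed. The other probe sets of PAX2 and EYA1, below 4 on all arrays, gave changes of -0.39 and 0.39. Those of GATA3 gave 1.77 and 2.35, that of PAX6 gave 5.61, and those of PAX8 went both ways.

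Eye and pigment genes had a median of 0.41, and FOXE3 was the 1 of 19 that passed over all genes. Adjusted over the list alone, 3 rose and 1 fell (adjusted p = 0.0167; adjusted p = 0.471 with an estimated correlation). Of 19 neural crest genes, with a median of 1.27, 5 rose and 1 fell when adjusted over the list alone (adjusted p = 0.00164; adjusted p = 0.114 with an estimated correlation). FOXD3, which is also a pluripotency gene, had a change of -3.89 ± 1.90 (-1.96 with the floor), and TFAP2B of 3.79 ± 1.00. Of 32 mesenchyme and matrix genes 1 rose when adjusted over the list alone, with a median of 0.84 and, by line, 1.40 in Shef3, 1.44 in H14 and -0.03 in Shef1 (adjusted p = 8.00e-07; adjusted p = 0.471 with an estimated correlation). MGP and FBLN5 had changes of 6.10 ± 3.56 and 3.07 ± 1.54, or 2.30 and 1.88 with the floor. Of 32 neuronal genes, with a median of 0.35, 1 rose when adjusted over the list alone (adjusted p = 0.00442; adjusted p = 0.471 with an estimated correlation), and ISL1 had a change of 3.71 ± 1.33.

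Camera called 5 further lists, with no member passing over all genes. BMP and TGF-beta targets had a median of 0.58 with 2 of 18 risen adjusted over the list alone (adjusted p = 0.00316; adjusted p = 0.448 with an estimated correlation), and MSX2 passed with the block at a change of 2.62 ± 0.77 (adjusted p = 0.176, and 0.0234 with the block). NOTCH pathway genes had a median of 0.64 with 2 of 18 risen and 1 fallen adjusted over the list alone (adjusted p = 0.0214; adjusted p = 0.448 with an estimated correlation), where HEY1 had a change of 1.97 ± 0.51 and HEY2 of -1.82 ± 0.35. WNT targets had a median of 0.43 with 1 of 18 risen adjusted over the list alone (adjusted p = 0.0167; adjusted p = 0.493 with an estimated correlation). Trophoblast genes had a median of 0.84 with 0 of 18 passing adjusted over the list alone (adjusted p = 0.0161; adjusted p = 0.448 with an estimated correlation). Ribosomal protein genes had a median of -0.35 with 0 of 26 passing adjusted over the list alone (adjusted p = 0.0218; adjusted p = 0.747 with an estimated correlation).

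Without Shef3 the calls of neurons (adjusted p = 0.104), eye and pigment (0.334) and ribosomal proteins (0.339) were lost, and without Shef1 that of WNT targets (0.200). After quantile normalisation that of ribosomal proteins was lost (0.481), and with the mean of probe sets those of trophoblast (0.0857), WNT targets (0.0688) and the NOTCH pathway (0.0904). Without dim genes those of eye and pigment (0.271) and the NOTCH pathway (0.0575) were lost, and with the floor of 4 that of eye and pigment (0.0522). The floor took the median to 0.08 for neurons, 0.68 for neural crest, -1.54 for endoderm and 0 for trophoblast and for eye and pigment. None of the 13 calls held with an estimated correlation, and fry gave an adjusted p of 0.0124 for neural progenitors and 0.0228 for endoderm. The other 15 lists did not pass in camera. Their medians were 0.65 for epidermis and simple epithelium, 0.32 for glia, 0.21 for retinoic acid and hedgehog targets, 0.01 for cholesterol synthesis, -0.01 for stress and apoptosis, -0.07 for endothelium and -0.08 for FGF signalling targets. They were -0.16 for HOX genes, -0.29 for blood and macrophages, -0.46 for striated muscle, -0.51 for hair cells, -0.51 for FGF ligands and receptors, -0.54 for the cell cycle, -0.56 for hypoxia and glycolysis and -0.57 for mesoderm. With the block the epidermis list (adjusted p = 0.0201) and the list of FGF ligands and receptors (adjusted p = 0.0458) also passed. Neither held with the block and an estimated correlation (adjusted p = 0.577 and 0.546), and the median of the FGF list was 0 with the floor. The test's direction was up where the median was negative for FGF signalling targets, endothelium, HOX genes and stress and apoptosis.

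The second comparison asks what changed over 14 days with FGF3 and FGF10. FOXE3 rose from -2.71 ± 0.39 (SD, n = 3) in hESC to 8.18 ± 0.97, and SIX6 from -1.53 ± 0.39 to 6.51 ± 0.77. SCUBE3, a secreted glycoprotein, rose from 5.48 ± 0.86 to 9.02 ± 0.54 and GFRA1 from 3.22 ± 1.00 to 7.25 ± 0.27. DNMT3L fell from 5.81 ± 1.15 to -3.48 ± 0.44, NLRP7 from 4.57 ± 0.81 to -3.96 ± 0.18 and S100A14 from 7.58 ± 0.36 to 3.35 ± 0.88.

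In total 35 genes were called, 19 higher and 16 lower, and 2369 had an unadjusted p below 0.05. With the block 115 were called, 60 higher and 55 lower, 34 of them among the 35. The block on only the 6 arrays of the 2 groups, chosen after seeing the data, called 10. Of 49 genes called without dim genes 37 were higher, of 31 with the mean of probe sets 12, and of 288 with array weights 126. The count was 0 without Shef3, 0 without H14 and 5 without Shef1, again with fewer arrays in every group. At an unadjusted p below 0.05 these fits gave 1433, 1284 and 3341 genes. Without a single array the number of genes called was 8 (hESC Shef3), 6 (hESC H14), 2 (hESC Shef1), 8 (FGF3+10 Shef3), 2 (FGF3+10 H14) or 10 (FGF3+10 Shef1). Both means lay below level 4 for 10 of the genes and 1 mean for 21. With the floor of 4, 123 genes were called, 54 higher and 69 lower, and 12 of the 123 were among the 35. The median log2 change over all genes was -0.19, and -0.06 after quantile normalisation.

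The log2 change was 10.89 ± 1.22 (SE, n = 3 and 3 arrays) for FOXE3 (adjusted p = 0.0209) and 8.04 ± 1.07 for SIX6 (adjusted p = 0.0356). ZFHX4-AS1 rose by 6.03 ± 0.58, CNTN6 by 5.52 ± 0.64, TSPAN11 by 4.85 ± 0.48, CNTN5 by 4.63 ± 0.56, GFRA1 by 4.03 ± 0.53, WNT5B by 3.95 ± 0.54 and SCUBE3 by 3.54 ± 0.48. CLSTN2 rose by 4.43 ± 0.58 (adjusted p = 0.0356, and 0.0530 with the block). DNMT3L fell by 9.29 ± 0.69 (adjusted p = 0.00461), NLRP7 by 8.53 ± 0.52 (adjusted p = 0.00185) and PDZK1 by 6.70 ± 0.84. LGALS12 fell by 6.31 ± 0.80, PROK2, a secreted signalling peptide, by 5.90 ± 0.83, NRROS by 5.25 ± 0.62 and RNF5 by 4.59 ± 0.48. S100A14 fell by 4.24 ± 0.51, NOSTRIN by 4.16 ± 0.58 and DPPA5 by 4.00 ± 0.36. With values below 4 set to 4, the change was 4.18 for FOXE3, 2.51 for SIX6, 1.84 for ZFHX4-AS1, 1.24 for CNTN6, 2.20 for TSPAN11, 0.69 for CNTN5, 2.26 for WNT5B and 3.54 for SCUBE3. It was -1.81 for DNMT3L, -0.67 for NLRP7, -1.75 for PDZK1, -0.06 for LGALS12, -0.79 for PROK2, -0.63 for NRROS, -0.72 for RNF5 and -3.47 for S100A14. NOSTRIN and DPPA5 had a change of 0 with that floor. The calls of FOXE3 (adjusted p = 0.136), SIX6 (0.0956), ZFHX4-AS1 (0.136), CNTN6 (0.301), CNTN5 (0.374), WNT5B (0.0515), DNMT3L (0.146), NLRP7 (0.333), LGALS12 (0.870), PROK2 (0.0921), NRROS (0.375) and RNF5 (0.123) were lost with it, and those of TSPAN11, CLSTN2, GFRA1, SCUBE3, PDZK1 and S100A14 held.

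Of 25 pluripotency genes none passed over all genes or adjusted over the list alone, and all 25 were lower on average. The median was -2.38, with -4.91 in Shef3, -1.50 in H14 and -0.37 in Shef1 (adjusted p = 2.54e-05; adjusted p = 0.663 with an estimated correlation). NANOG had a change of -7.60 ± 5.58 and LEFTY1, a NODAL antagonist, of -7.51 ± 2.21 (adjusted p = 0.626 and 0.225), and with the floor that of NANOG was -3.73. SOX2 had a change of -1.14 ± 0.77 (adjusted p = 0.595). Of 24 endoderm genes none passed over all genes and 13 fell when adjusted over the list alone, with a median of -3.16 (adjusted p = 1.06e-09; adjusted p = 0.0884 with an estimated correlation). CER1 and APOC3 had changes of -6.32 ± 2.30 and -5.84 ± 2.70, the latter -1.06 with the floor. Of 21 striated muscle genes 4 fell when adjusted over the list alone, with a median of -0.88 (adjusted p = 0.0188; adjusted p = 0.128 with an estimated correlation). NPPA passed only with the block at a change of -3.44 ± 0.72 (adjusted p = 0.109, and 0.0424 with the block), and had a change of 0 with the floor.

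Neural progenitor genes had a median of 1.48, with 2.26 in Shef3, 0.83 in H14 and 1.59 in Shef1. SIX6 was the 1 of 32 that passed over all genes, and 14 rose when adjusted over the list alone (adjusted p = 6.65e-12; adjusted p = 0.0513 with an estimated correlation). PAX6 had a change of 4.51 ± 1.01 (adjusted p = 0.130). Of 30 otic and preplacodal genes none passed over all genes and 10 rose when adjusted over the list alone, with a median of 1.17, or 0.32 with the floor of 4 (adjusted p = 6.78e-09; adjusted p = 0.0884 with an estimated correlation). EYA2, EYA4 and EYA1 had changes of 4.22 ± 0.80, 4.15 ± 1.10 and 3.14 ± 0.83 (adjusted p = 0.0922, 0.187 and 0.187), and with the floor those of EYA2, EYA4 and EYA1 were 1.35, 0.67 and 1.59. DLX5 had a change of 3.61 ± 0.70 (adjusted p = 0.0963, and 0.0444 with the block), which was 0.81 with the floor (adjusted p = 0.540). PAX2 had a change of 1.96 ± 0.95 (0.30 with the floor), GATA3 of 1.40 ± 0.62 and PAX8 of -0.02 ± 0.40. The other probe sets of PAX2 and EYA1, below 4 on all arrays, gave 0.03 and 1.49, and that of PAX6 gave 6.32. Eye and pigment genes had a median of 0.62, FOXE3 and SIX6 were the 2 of 19 that passed over all genes, and 3 rose when adjusted over the list alone (adjusted p = 0.000116; adjusted p = 0.284 with an estimated correlation).

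Of 19 neural crest genes, with a median of 0.51, 2 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0155; adjusted p = 0.128 with an estimated correlation). NOTCH pathway genes had a median of 0.60 with 2 of 18 risen and 1 fallen adjusted over the list alone (adjusted p = 0.00315; adjusted p = 0.307 with an estimated correlation). BMP and TGF-beta targets were called higher although their median was -0.01, with a mean of 0.38 and 2 of 18 risen adjusted over the list alone (adjusted p = 0.0263; adjusted p = 0.663 with an estimated correlation). MSX2 passed there with the block at a change of 2.35 ± 0.77 (adjusted p = 0.274, and 0.0297 with the block). Without Shef3 the call of neural crest (adjusted p = 0.0751) was lost, and without H14 those of striated muscle (0.0528) and of BMP and TGF-beta targets (0.106). Without dim genes that of eye and pigment was lost (0.133). Without Shef1 14 lists were called in place of 9. The floor took the median to 0.81 for neural progenitors, 0.30 for neural crest, 0.04 for eye and pigment and 0 for striated muscle. None of the 9 calls held with an estimated correlation. Fry gave an adjusted p of 0.0138 for neural progenitors, 0.0138 for endoderm, 0.0362 for the otic list and 0.0229 for striated muscle. With the block the trophoblast list (adjusted p = 0.0242) and ribosomal protein genes (adjusted p = 0.0385) passed too. Neither held with the block and an estimated correlation (adjusted p = 0.180 and 0.870), and the trophoblast median was 0 with the floor. The test's direction was up where the median was negative for FGF signalling targets, neurons, endothelium, glia, retinoic acid and hedgehog targets and cholesterol synthesis, none of which passed.

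Both responses called 26 genes in the same direction, 16 higher and 10 lower. Among them were FOXE3, CLSTN2, GFRA1, DNMT3L, NLRP7 and S100A14. Both comparisons use the same 3 hESC arrays. Unchanged groups simulated against shared controls gave an overlap of 0.02 genes on average over 50 draws, and independent lists would share 0.0221 higher and 0.0138 lower genes. No gene was changed in that simulation, so hardly any could be called. Its overlap therefore cannot show how many real calls would be shared through the controls. The log2 changes correlated at 0.876 across genes against 0.499 in the simulation, and their covariance was 0.924 against 0.214, a difference of 0.710. The shared genes of the 2 day 14 responses numbered 0 without Shef3, 0 without H14, 4 without Shef1 and 87 with the cell line as replicate block. The day 14 arrays also share their cell lines. With the noise correlated within lines as the deviations were, the simulation gave 0.02 genes, a correlation of 0.673 and a covariance of 0.229, a difference of 0.695. The overlap in this simulation has the same limit. With 3 hESC arrays the controls could not be split, and part of the excess may come from shared controls and lines.

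The third comparison asks what the FGFs added to the medium, between the day 14 groups. No gene was called. The smallest adjusted p in limma was 1.00, and 0.699 with the block. At an unadjusted p below 0.05 there were 300 genes, and 537 with the block, against 987 expected by chance. The paired fit of the 6 day 14 arrays, chosen after seeing the data, called 0 genes with 989 at an unadjusted p below 0.05, and the trended and robust variance and the random block also called 0. Array weights called 0 with 1400 at an unadjusted p below 0.05. SIX6, an eye field factor, stood at 6.51 ± 0.77 (SD, n = 3) with FGFs and 3.93 ± 2.49 without, a change of 2.58 ± 1.07 (SE), or 1.64 with the floor of 4. Most of this came from H14, from 1.20 without FGFs to 6.52 with them, against 4.51 to 5.74 in Shef3 and 6.07 to 7.27 in Shef1. Targets of FGF signalling had a median change of 0.01 over 22 genes with 0 passing adjusted over the list alone. By line the median was 0.51 in Shef3, 0.04 in H14 and -0.52 in Shef1. DUSP6, SPRY4, ETV4 and ETV5, feedback regulators and transcription factors induced by FGF, had changes of 0.20 ± 0.53, 0.24 ± 0.82, -0.03 ± 1.34 and 0.06 ± 0.57, and with the floor that of ETV4 was 0.49.

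Among otic genes, the change was 0.36 ± 0.40 for PAX8, 0.86 ± 0.95 for PAX2, 0.58 ± 0.70 for DLX5, -0.43 ± 0.83 for EYA1 and -0.13 ± 0.62 for GATA3. It was 0.64 ± 1.01 for PAX6, 0.80 ± 0.77 for SOX2 and 1.15 ± 5.58 for NANOG. With the floor it was 0.30 for PAX2, -0.28 for EYA1 and 0.30 for NANOG. The other probe sets of PAX2 and EYA1, below 4 on all arrays, gave 0.42 and 1.09, so that of EYA1 had the opposite sign. The transcripts of the added factors themselves had low levels: FGF3 stood at -2.18 ± 0.77 with FGFs and -2.95 ± 0.85 without, and FGF10 at 1.35 ± 2.07 and 1.69 ± 1.59. The genes with the highest moderated t were TPSAB1, CDH20, SNORA71A, CD3D and DCSTAMP, with changes of 1.95, 3.08, 1.67, 1.54 and 1.79. Those with the lowest were SI, ASZ1, LINC00658, SLIT2-IT1 and ORF1, with changes of -2.76, -1.92, -1.90, -2.41 and -1.89. All 10 had means below level 4 in both groups, and none passed.

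Camera called 5 lists, with no member passing over all genes or adjusted over the list alone. Mesenchyme and matrix genes were lower with FGFs, at a median of -0.98 and with 31 of 32 members lower on average (adjusted p = 8.30e-17; adjusted p = 0.399 with an estimated correlation). By line the median was -0.10 in Shef3, -1.41 in H14 and -1.43 in Shef1, and MGP had a change of -4.91 ± 3.56 (-0.90 with the floor). HOX genes had a median of -0.64 (adjusted p = 8.81e-06; adjusted p = 0.399 with an estimated correlation), with -1.60 in Shef3, 0.33 in H14 and -0.74 in Shef1. Neuronal genes had a median of -0.43 with 28 of 32 lower on average (adjusted p = 1.63e-05; adjusted p = 0.399 with an estimated correlation), with 0.18 in Shef3, -0.90 in H14 and -0.37 in Shef1. Stress and apoptosis genes had a median of -0.25 (adjusted p = 0.00147; adjusted p = 0.577 with an estimated correlation), with 0.09 in Shef3, -0.51 in H14 and -0.39 in Shef1. Eye and pigment genes had a median of 0.43 (adjusted p = 0.00687; adjusted p = 0.523 with an estimated correlation), with 1.73 in H14, -0.26 in Shef3 and -0.06 in Shef1. RAX, an eye field factor, had a change of 3.23 ± 1.92 (0.80 with the floor). Without H14 the calls of neurons (adjusted p = 0.569), eye and pigment (0.827) and stress and apoptosis (0.594) were lost, without Shef3 that of HOX genes (0.338) and without Shef1 that of stress and apoptosis (0.0637). Without dim genes that of eye and pigment was lost (0.211). In total 8 lists were called without Shef3, 8 after quantile normalisation, 11 without dim genes and 13 with the floor of 4. The floor took the median to -0.29 for neurons, -0.15 for HOX genes and 0.04 for eye and pigment. Fry called 0 lists. With the block camera called 11, adding pluripotency at a median of 0.53, neural crest at -0.37, epidermis at -0.35, striated muscle at -0.45, glia at -0.35 and BMP and TGF-beta targets at -0.27 (adjusted p = 0.0385 for each). None of these 6 held with the block and an estimated correlation, where the adjusted p was 0.835 for pluripotency, 0.654 for epidermis and 0.546 for the others. With the floor, without the block, the medians were 0.28 for pluripotency, -0.20 for neural crest, -0.22 for epidermis, -0.08 for glia and 0 for striated muscle. The median of neural progenitors, at -0.03, had the opposite sign to their mean of 0.11. The test's direction was down where the median was 0.01 for FGF signalling targets and for blood and macrophages.

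**Figure D3:**
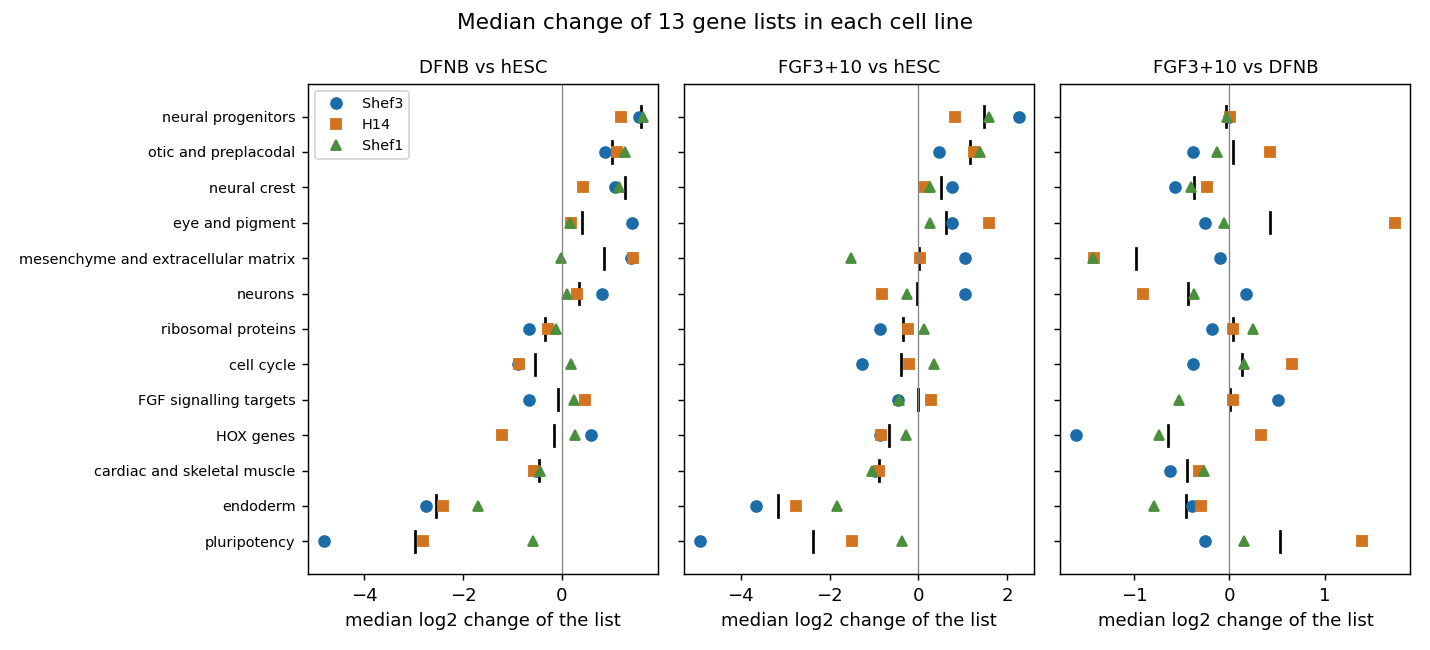
Median log2 change of 13 gene lists in each comparison, with 1 point per cell line and a black bar at the median of the mean changes. Pluripotency medians against hESC run from -4.91 in Shef3 to -0.37 in Shef1 in FGF3+10, whereas neural progenitor medians lie above 0 in every line in both day 14 groups.

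The cell lines differed in 90 genes by the F test over lines, with 4012 genes at an unadjusted p below 0.05. ZNF667-AS1, an antisense RNA, averaged 8.13 ± 0.12 (SD, n = 3) in Shef3, 8.39 ± 0.22 in H14 and -3.73 ± 0.31 in Shef1 (adjusted p = 9.21e-05). HEPH, a copper-dependent ferroxidase, averaged 9.09 ± 0.47, 9.37 ± 0.22 and 0.55 ± 0.43. ZNF558 was low in Shef3, at -1.80 ± 0.84 against 6.98 ± 0.43 in H14 and 6.94 ± 0.22 in Shef1. MGMT, a DNA repair gene, was low in H14, at -0.11 ± 0.97 against 6.72 ± 0.87 in Shef3 and 5.72 ± 0.85 in Shef1. MAGEH1 was high in H14 alone, at 6.84 ± 0.19, and NNAT, an imprinted gene, in Shef3 alone, at 7.51 ± 0.43. Shef1 had the lowest mean in 62 of the 90 genes and the highest in 17. Leaving out any single array lowered the count, to between 16 (without DFNB Shef1) and 54 (without hESC Shef3). None of the 90 was among those called between DFNB and hESC. That comparison has no line block and counts line differences as spread, which hinders such calls, so the lack of overlap says little. The higher poly-A spike-ins of the Shef1 arrays coincide with the line, so a labelling batch and the line cannot be told apart there.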

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

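The tests of day 14 changes between lines, of the pluripotency list in Shef1, of the spike-ins and of the paired day 14 arrays were chosen after the results were seen, and the other splits of the arrays were planned.

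The day 14 change of a list differed between lines in 25 of 84 camera tests, of 28 lists in 3 pairs of lines. None held with an estimated correlation, where the smallest adjusted p was 0.839, and no single gene was called. Fry gave 3 calls, all for neural progenitors, with a median difference of 1.02 for Shef1 minus H14 (adjusted p = 0.00543), 0.09 for Shef1 minus Shef3 (0.0274) and -0.44 for H14 minus Shef3 (0.0226). For Shef1 minus Shef3 camera's direction was down, without a call (adjusted p = 0.492), and fry's direction is not given here. Values are the median difference in log2 change. Shef1 minus Shef3 gave 3.89 for pluripotency, 1.42 for the cell cycle, 1.38 for WNT targets, 0.87 for hypoxia and glycolysis and 0.75 for ribosomal proteins. It gave -1.99 for mesenchyme and matrix, -1.14 for neurons, -1.04 for eye and pigment and -0.34 for epidermis. Shef1 minus H14 gave 1.75 for pluripotency, 1.00 for the cell cycle, -1.68 for mesenchyme and matrix, -1.39 for epidermis, -0.33 for FGF signalling targets and -0.26 for retinoic acid and hedgehog targets. H14 minus Shef3 gave 2.89 for pluripotency, 1.31 for FGF signalling targets, 1.25 for epidermis, 0.80 for stress and apoptosis, 0.73 for hypoxia and glycolysis, 0.52 for ribosomal proteins and 0.43 for the cell cycle. It gave -1.37 for neurons, -1.06 for HOX genes and -0.44 for neural progenitors.

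With values read as log2, the median pluripotency gene at day 14 kept 66.8% of its day 0 level in DFNB and 77.4% in FGF3+10 in Shef1, against 14.3% and 35.2% in H14 and 3.58% and 3.32% in Shef3. A constant shift of the Shef1 arrays by a labelling batch would raise their hESC array as well. The median of that array lay at -0.38 from the other hESC arrays (95% bootstrap interval -0.73 to -0.10 over correlated genes), against 0.40 for Shef3 and 0.08 for H14. At day 14 the excess of Shef1 was 2.43 over the mean of the other lines, 3.43 over Shef3 and 1.45 over H14. But 1 hESC array of the line gives no spread between arrays, so a batch stays open. A smaller range of change on the Shef1 arrays could shrink other lists too, and stays open for the same reason, although the neural progenitor list changed there by 1.12 times its change in the other lines (0.723 to 2.13 over genes), where fry called that list different between each pair of lines, and the pluripotency list by 0.127 times. A share of unchanged undifferentiated cells may remain in the Shef1 cultures, yet it would keep each gene of these cells near that share, whereas in Shef1 DNMT3L and S100A14 lay below 4 on both day 14 arrays, drops of at least 3.09 and 3.32 on the log2 scale with those values set to 4, and of 21 list members at 6 or more in hESC Shef1, 3 (DPPA2, LEFTY1 and PRDM14) kept less than 50% of the median share of the 21 (66.2% and 79.6%) on both arrays. Of 3 tests tried in turn, that count of 3 rested on a bound set with the levels in view. In the second, 18 of 3317 genes at 8 or more on all hESC arrays lay as low, against a bound of 200.4. That bound came from the spread within groups, which includes differences between lines, so it was too loose to decide. The third used limma's moderated spread, which includes them too. There 1 of 8041 genes, DNMT3L, lay below the share beyond its own spread (adjusted p = 0.0452, from day 14 values below 4). These tests could hardly detect a shortfall, so a share of unchanged cells stays open. A difference of the line itself was not tested and stays open too.

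Fewer genes than chance had an unadjusted p below 0.05 between FGF3+10 and DFNB, 300 against 987. Spread between lines and days in the shared variance may be the cause: the paired fit of the 6 day 14 arrays alone gave 989, with a median standard error of 0.257 against 0.484, and called 0 genes. The block on all 9 arrays gave 537 and the 6 arrays without it 352, so neither step alone accounts for the move, and the parts of lines and days were not separated. With array weights there were 1400, above the 987, and 0 were called, so an excess of small p-values depends on the model.

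The higher poly-A spike-ins of Shef1 could come from scaling whole arrays to a common median, which would raise the hybridisation spike-ins too. Those lay at -0.41 relative to the other lines, against 2.12 for the poly-A ones, which argues against it. The amount of spike-in added and the amount of RNA labelled stay open and were not tested.

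Between DFNB and hESC the real split called 40 genes and the highest of the other splits 1. For FGF3+10 against hESC these were 35 and 0. Of 10 splits, 1 gave as many genes as the real one in each, the real one itself, and 10 splits are too few for a share under 0.05. For FGF3+10 against DFNB all 10 splits gave at least the real count of 0. The highest called 128, with both Shef3 arrays on 1 side and both Shef1 arrays on the other, which points to a structure of the samples by line. Of the 4 splits that part all 3 lines, those other than the real one called 0 in each comparison, and the remaining splits put arrays of the same line together. For the cell lines, 1 of 36 regroupings within conditions, the real one, gave 90 genes, and the highest other gave 78. That share lies under the 0.05 set beforehand, but it is the smallest that 36 regroupings allow. A regrouping within conditions can keep all arrays of 1 line together, so its count can include line differences. The 78 genes of another regrouping are therefore not a count expected by chance alone. By the rule set beforehand the result argues against chance for the 90 genes as a set, though not for each gene.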

How the results depend on the processing

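The floor of 4, its combination with the block, the trended and robust variance with the block, and the paired fit of 6 arrays were chosen after the results were seen. Array medians were already equal, so centring moved nothing. The pseudocount did not apply to log values and was not run. In these arrays signal near background limits what can be measured. No called gene named here changed sign and no called list changed the direction of its test, but some changes that did not pass changed sign, as did the medians of eye and pigment genes and of BMP and TGF-beta targets under some settings. Most calls were lower, not higher, with array weights in both comparisons with hESC. In FGF3+10 against hESC this was also so with the mean of probe sets, with every probe set and with the floor of 4. In both comparisons it was so without some of the single arrays. The counts of called genes moved with the variance model, the floor and the lines left out, and the cause was not tested.

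Between DFNB and hESC the 40 genes became 110 without dim genes, 189 with the cell line as replicate block, 396 with a random block, 161 with a trended and robust variance, 1647 with array weights, 184 with the floor of 4, 426 with floor and block, 822 with trend, robust variance and block, 26 on the 6 arrays alone and 4 on these with the block. Leaving out an array of these groups or a line gave 0 to 33, and an array of the third group 25 to 72. For FGF3+10 against hESC the 35 genes became 115 with the block, 250 with a random block, 81 with trend and robust variance, 288 with array weights, 123 with the floor, 227 with floor and block, 419 with trend, robust variance and block, 15 on the 6 arrays and 10 on these with the block. Leave-outs gave 0 to 10, and of the third group 24 to 32. For FGF3+10 against DFNB every alternative run called 0.

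The 90 genes differing between cell lines became 57 after quantile normalisation, 515 without dim genes, 208 with the mean of probe sets, 467 with the floor and 615 with trend and robust variance, and 16 to 54 without single arrays. The 26 shared genes of the 2 day 14 responses became 45 without dim genes, 87 with the block and 116 with the floor, and 0 to 4 without a line.

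Lists called went from 13 to 0 with an estimated correlation and 2 with fry between DFNB and hESC (11 to 16 without a line), and from 9 to 0 and 4 between FGF3+10 and hESC (10 to 14). For FGF3+10 against DFNB they went from 5 to 0 with an estimated correlation and 0 with fry, 8 after quantile normalisation, 11 without dim genes, 11 with the block and 13 with the floor (4 to 8 without a line).

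Of 20 named genes called between DFNB and hESC, 19 kept their call with the block, 16 after quantile normalisation, 17 with the mean of probe sets and 8 of 16 tested with the floor. For FGF3+10 against hESC these were 19, 19, 15 and 6 of 18. Without Shef3 or H14 none kept it, and without Shef1 2 did in each comparison. Apart from those given, the block changed no other call of a gene or list named here.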

Other observations

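The genes and values here were chosen after the results were seen.

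ZFP42, a pluripotency marker known as REX1, was low on every Shef1 array, hESC included. Its probe set stood at -0.48 in hESC Shef1 against 10.47 in Shef3 and 9.23 in H14, and the other 2 probe sets of the gene at -3.65 and -4.37 in hESC Shef1 against 8.74 and 8.49 in Shef3. On the same Shef1 hESC array NANOG stood at 10.73 and SOX2 at 11.11. DNMT3L, which fell in both day 14 groups, went from 7.09 to -2.41 in Shef1 in DFNB, a drop of at least 3.09 with the lower value set to 4, while L1TD1 kept 96.5% and LIN28A 108% of their day 0 level on that array.

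With FGFs against DFNB alone, DUSP6, ETV4 and ETV5 were higher in Shef3, by 1.22, 0.96 and 0.96, and in H14, by 0.36, 0.52 and 0.22. In Shef1 the differences were -0.97, -1.56 and -0.99. SPRY4 had the same signs. ETV4 in Shef1 went from 3.72 in DFNB to 2.16 with FGFs, both below the floor of 4, so its difference vanishes with the floor. In H14 other ETV5 probe sets went the other way, from 7.02 to 6.86, 5.78 to 5.64 and 4.65 to 4.45, and another rose from 0.99 to 2.83. Each of these differences is between single arrays and was not tested.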
